A study of Mus musculus with 3 samples.

How the data were processed

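Small RNA libraries were made with the Illumina small RNA protocol from total RNA of snap-frozen epididymal fat, per the labels' protocols. The values used here are deposited log2 values, 1 per mature miRNA and mouse, in 1 table of 1251 miRNAs and 3 columns, per the file headers. Per the series' design text, the authors processed reads with the Gunaratne next-generation pipeline, mapped about 13.8 M reads per sample to mouse build mm10, normalized counts to total usable reads and added 40 counts. The aligner, its version and the miRNA annotation are not given in the sources used here. The build mm10 is also named per the submitters' processing notes.

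The values depart from that description in 2 ways. The lowest deposited log2 value is 3.32, which is 10 on the linear scale, and 260 values lie between 10 and 40, so a constant of 40 was not what the values hold. The sorted columns are nearly equal: 85 of the top 100 ranks have the same value in the 3 mice within 1e-06, as do 121 of the 336 ranks above the floor (36.0%), and the largest difference at any rank is 0.34. That pattern resembles what quantile normalization leaves, a step that no source used here states. It makes totals, the share of the top miRNAs and nearly the number detected equal by construction, and a difference between mice is in essence a difference of ranks. Library depth could not be recovered, so no counting interval is given. The basis of the 6.75% EPA (of energy or of weight) is not stated.

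Each value was turned to a linear normalized count as the power of 2 minus 10, and logs were taken after adding 10 back, which is the deposited scale. The design fixed before the data were examined had assumed a constant of 40. That constant became an alternative, and 10, listed at that time as the other choice, is now the value used. Differences on this scale understate those of miRNAs near the floor. A miRNA counted as seen in a mouse when it stood above the floor. Shares are percentages of the summed linear values of a mouse. Tests across miRNAs used those with a mean of at least 100 above the floor, 194 in number.

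Abundance, detection, families and agreement were described by mean and SD over 3 mice, with no test. Arm ratios of hairpins with both arms listed (425, of which 129 had the larger arm at a mean of at least 100) were tested against 0 with limma 3.58.1 in R 4.3.3, moderated and two-sided. Variation between mice was tested with limma as the residual variance of each miRNA (2 degrees of freedom) against its trended prior, which had 2.06 degrees of freedom. Both used Benjamini-Hochberg adjustment with a threshold of 0.05. List levels and list differences between mice were given as percentiles of 10000 random lists, the latter matched on level within windows of 21 neighbours. List contrasts used an exact sign-flip test, whose smallest p is 0.25. Clustered pairs were set against 10000 random sets of pairs, one-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 11.

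The marker lists (adipogenesis-promoting and inhibiting, brown and beige promoting and inhibiting, leukocyte, endothelial, stromal, erythroid, striated muscle, epithelial, testis, hepatocyte, pancreas, neuronal, and raised or lowered in obese fat), seed families and genomic clusters were fixed before the data were examined. Names were matched to rows directly or by older forms, such as miR-145a-5p for miR-145-5p. miR-885-5p and miR-422b had no row. The miRNAs named were set by a rule fixed at the same time. It takes the 20 with the highest mean, up to 4 highest members of each list, the 10 largest families, the 5 largest SDs where under 5 pass the variance test, the 5 smallest SDs among the 100 most abundant, the 5 hairpins that lean most to each arm and the 3 nearest to equal. It adds 9 miRNAs tied to thermogenic fat: miR-30b-5p, miR-30c-5p, miR-378a-3p, miR-193b-3p, miR-365-3p, miR-455-3p, miR-455-5p, miR-133a-3p and miR-34a-5p. Others were named after their values were seen, among them miR-375 in the arm test, miR-1a-3p with its cluster partner and further members of the epithelial list.

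Hairpin positions come from GENCODE M21 on GRCm38, the assembly of mm10. They were found for 73 of 74 named miRNAs, and the table itself gives none.

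The tests were tried on simulated data. The arm test recovered 64 of 64 changed hairpins among 129 with 1 false call. The variance test recovered 0 of 10 variable miRNAs among 194, and with a robust prior, added after this, 10 of 10 with 0 false calls. In that simulation all other miRNAs had the same noise, unlike the data. A shifted list of 10 miRNAs among 363 lay at percentile 100 for its range between mice.

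Alternatives were another pseudocount (1 or 40), values as deposited, other filters (none, or a mean of at least 1000), detection at 10 or 100, median-ratio scaling, the prior with or without trend, another pool for random lists and leaving out each mouse. The robust prior, pseudocount 40, deposited values with 10 added for the arms, identical rows counted once, all alternatives for the list contrasts, the brown and beige promoting list without shared members, clusters without the Dlk1-Dio3 region, and list ranges between mice and clusters with a mouse left out were chosen after seeing the data. All samples of the group were used. A single group with no control was analysed here, so comparisons of diets were not made.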

Results

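Mature microRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured by small RNA sequencing in visceral white fat, taken from the epididymal depot, of 3 C57BL/6J mice. The mice, numbered 1, 3 and 9, had eaten a high-fat diet enriched in eicosapentaenoic acid (EPA), an omega-3 fatty acid of fish oil. Fat gave 45% of the energy, protein 20% and carbohydrate 35%, and the diet held 6.75% EPA. Feeding lasted 11 weeks from an age of 5 to 6 weeks, and the tissue was taken after a 4 h fast. The stated purpose was to find which miRNAs this fat expresses on the EPA diet. One group was analysed here and no control diet, so no value below measures an effect of EPA. Nothing but the sample titles and a note of 3 samples per group says that the 3 samples are separate animals. The p-values for arms, variation and list contrasts therefore measure only the spread between these samples, which may be technical. Those for genomic clusters and GC content come from random draws or shuffles of miRNAs and do not measure that spread. The depth of each library is unknown, as the values were normalized before deposit.

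The fat was dominated by a small set of miRNAs that includes known regulators of adipocytes, muscle lineages and cell growth. miR-22-3p led with 14.7% ± 4.67 of the summed normalized value (SD, n = 3), followed by miR-26a-5p with 11.2% ± 5.33. Next came the paired Hox-cluster miRNAs miR-10b-5p with 7.90% ± 2.43 and miR-10a-5p with 6.50% ± 1.54. miR-143-3p, which promotes adipocyte differentiation, held 5.87% ± 0.670. On the log2 scale miR-22-3p averaged 18.37 ± 0.52, miR-26a-5p 17.95 ± 0.63, miR-10b-5p 17.48 ± 0.50, miR-10a-5p 17.23 ± 0.34 and miR-143-3p 17.10 ± 0.17.

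Among the next ranks were let-7c-5p, let-7a-5p and let-7f-5p of the growth-restraining let-7 family. let-7c-5p averaged 16.65 ± 0.12 log2 units, let-7a-5p 16.34 ± 0.28 and miR-181a-5p 16.21 ± 0.29 (SD, n = 3). miR-30a-5p stood at 16.18 in each of the 3 mice. miR-378a-3p, encoded in an intron of the mitochondrial coactivator gene Ppargc1b, averaged 16.07 ± 0.63. miR-191-5p followed with 15.74 ± 0.23, miR-30d-5p with 15.62 ± 0.13, miR-125a-5p with 15.38 ± 0.15 and let-7f-5p with 15.34 ± 0.20. The rest of the 20 most abundant were miR-3107-5p and miR-486-5p (15.13 ± 0.43 each), miR-27b-3p (15.07 ± 0.08), miR-99b-5p (14.85 ± 0.32), miR-133a-3p (14.78 ± 2.47) and miR-30c-5p (14.63 ± 0.20).

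The leading positions were not the same in the 3 mice. miR-26a-5p held rank 1 in mouse 1 at 18.67 log2 units and rank 3 in mice 3 and 9 at 17.58. miR-22-3p held rank 1 in mice 3 and 9 at 18.67 and rank 2 in mouse 1 at 17.77. Of the 19 neighbouring pairs among the 20 most abundant miRNAs, 4 kept their order in all 3 mice: miR-143-3p above let-7c-5p, let-7c-5p above let-7a-5p, let-7a-5p above miR-181a-5p, and miR-30d-5p above miR-125a-5p. The order of neighbours within the top 5 therefore lay within the spread between mice. Pairs further apart were steadier. In every mouse miR-22-3p stood above miR-10b-5p, miR-10a-5p and miR-143-3p, and miR-26a-5p above miR-10a-5p and miR-143-3p. No test was made on these levels.

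**Figure D1:**
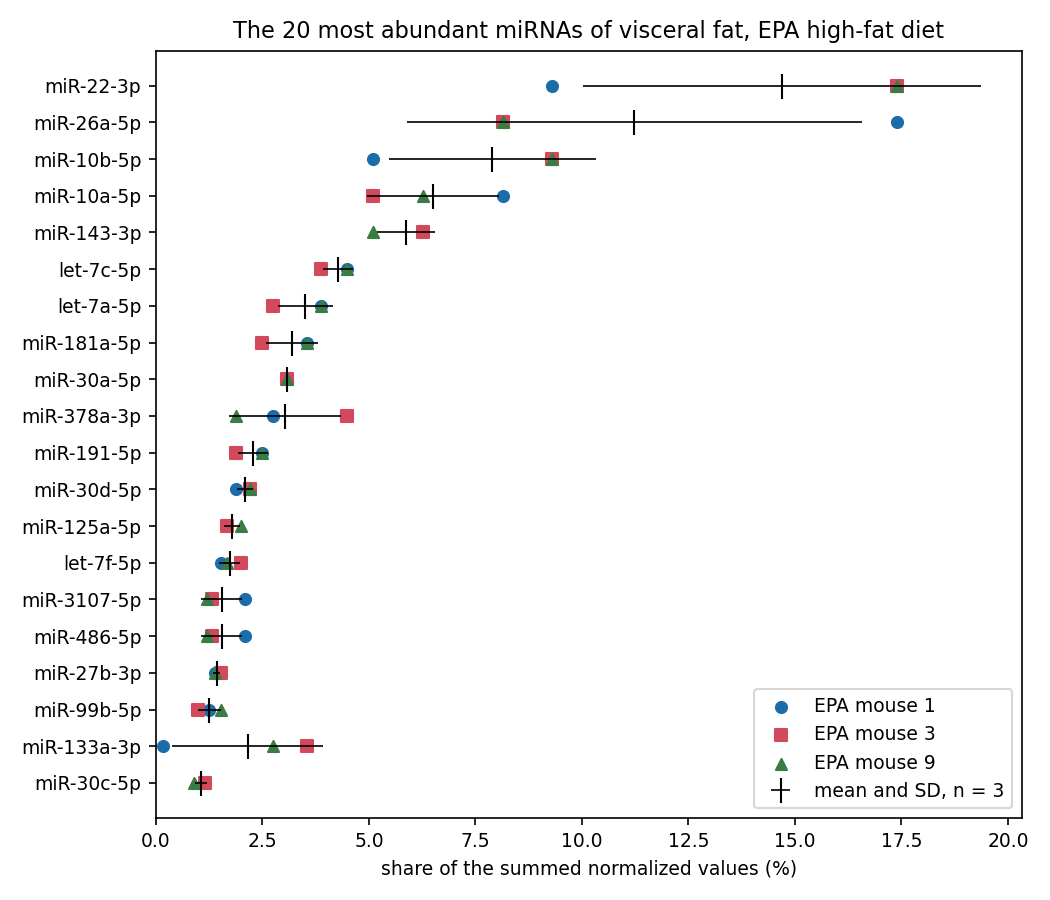
Share of the summed normalized value (percent, linear axis) of the 20 most abundant miRNAs, with 1 symbol per mouse and the mean and SD of 3 mice in black. miR-22-3p spans 9.30% to 17.4% and miR-26a-5p 8.15% to 17.4%, while miR-133a-3p stands at 0.162% in mouse 1 and at 3.54% and 2.76% in mice 3 and 9.

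The hairpins of the leading miRNAs lie, on mouse assembly GRCm38 (mm10), in a mixture of host genes and intergenic DNA. Mir22 spans chromosome 11 from 75463716 to 75463810 and overlaps an exon of Mir22hg and Tlcd2 annotation. miR-26a-5p comes from Mir26a-1 on chromosome 9 (119031796 to 119031885, an intron of Ctdspl) and Mir26a-2 on chromosome 10 (126995530 to 126995613, within Ctdsp2), whose products are identical. Mir10b lies on chromosome 2 from 74726070 to 74726137 in an intron of Hoxd3, and Mir10a on chromosome 11 from 96317165 to 96317274 outside any gene annotated on its strand. Mir143 lies on chromosome 18 from 61649196 to 61649258, intergenic on its strand, and Mir378a on the same chromosome from 61397835 to 61397900 in an intron of Ppargc1b. Mir486, in an intron of the ankyrin gene Ank1, covers chromosome 8 from 23142555 to 23142682, and Mir3107 covers 23142573 to 23142662 on the opposite strand. The rows of miR-486-5p and miR-3107-5p held identical values, so reads of the 2 cannot be told apart and their shared level is counted under both names.

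Most annotated miRNAs were not seen in this fat. Of 1251 miRNAs listed, 287 stood above the floor of the scale in all 3 mice, 32 in 2 mice and 44 in 1 mouse, and 888 stood at the floor in all. Mouse 1 had 316 miRNAs above the floor, mouse 3 had 317 and mouse 9 had 336. Among those seen in 1 mouse, 28 were seen in mouse 9 and the highest reached 26.8 normalized counts above the floor. A miRNA at the floor was not detectable in these libraries, which does not show that it is absent.

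The most abundant miRNA of each mouse, miR-22-3p or miR-26a-5p, took 17.4% of the summed value. The top 10 miRNAs took 63.9% and the top 20 took 80.4% (n = 3). These shares are nearly the same in the 3 mice because the columns hold nearly one common set of values, so their SD says nothing of the tissue. Counting rows with identical values, such as miR-486-5p and miR-3107-5p, once gives 65.2% for the top 10.

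Seed families, fixed before the data were examined, group miRNAs by the part that selects targets. The grouping leaves out single miRNAs such as miR-22-3p (14.7%) and miR-143-3p (5.87%). Within it the miR-10 family held 14.4% ± 1.15, the let-7 and miR-98 family 12.6% ± 0.963 and the miR-26 family 11.6% ± 5.33 (SD, n = 3). The miR-30 family, which promotes adipogenesis, followed with 6.65% ± 0.188, then the miR-181 family with 3.46% ± 0.606 and the miR-378 family with 3.14% ± 1.36. Smaller shares belonged to the miR-125 family (2.49% ± 0.151), the miR-27 family (1.66% ± 0.0764), miR-99 and miR-100 (1.63% ± 0.265) and the miR-15, miR-16 and miR-195 family (1.30% ± 0.0386).

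The miR-26 share was 17.7% in mouse 1 against 8.54% and 8.45% in mice 3 and 9. The miR-378 share was 4.62% in mouse 3 against 2.84% and 1.95% in mice 1 and 9. The miR-10 family exceeded let-7 and miR-98 in 3 of 3 mice, and miR-26 exceeded miR-30 in 3 of 3. let-7 and miR-98 exceeded miR-26 in 2 of 3 mice. The same count held for miR-181 over miR-378, miR-378 over miR-125, and miR-27 over miR-99 and miR-100, so those orders did not hold against the spread between mice.

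Across the 194 miRNAs with a mean of at least 100 normalized counts above the floor, the mice had similar profiles. Spearman's rho across miRNAs, which are not independent replicates, was 0.960 between mice 1 and 3, 0.964 between mice 1 and 9 and 0.964 between mice 3 and 9. The SD of the log2 difference was 0.84, 0.88 and 0.78 for these pairs. The number of miRNAs that differed by at least 1 log2 unit was 12 between mice 1 and 3, 13 between mice 1 and 9 and 16 between mice 3 and 9.

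Each miRNA hairpin yields a 5p and a 3p strand, and nearly every hairpin in this fat kept one strand far above the other. The 5 hairpins with the highest log2 ratio of 5p to 3p on this scale were miR-10b at 13.76 (SE 0.28, n = 3), miR-191 at 12.41 (SE 0.16), miR-10a at 11.44 (SE 0.21), miR-30d at 10.81 (SE 0.50) and let-7g at 10.33 (SE 0.22). The 5 with the lowest were the adipogenic miR-143 at -11.06 (SE 0.24), miR-29a at -10.68 (SE 0.14), the miR-23a hairpin at -10.04 (SE 0.17), miR-22 at -9.81 (SE 0.22) and miR-127 at -9.49 (SE 0.21). For miR-191 the 3p arm, and for miR-29a and miR-23a the 5p arm, stood at the floor in all mice. The lower arm also stood at the floor in mice 1 and 3 for miR-10b, in mouse 1 for miR-30d and in mouse 3 for let-7g and miR-127. These ratios rest on the floor, and their place in the order is not set. Nearest to equal were miR-361 at 0.22 (SE 0.16), miR-872 at -0.33 (SE 0.26) and miR-350 at -0.38 (SE 0.15).

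Of 129 hairpins tested, 66 had the 5p arm higher and 59 the 3p arm higher by limma's moderated one-sample test, two-sided, with Benjamini-Hochberg adjusted p below 0.05. The adjusted p was 3.79e-06 for miR-10b (5p higher in 3 of 3 mice), 3.97e-06 for miR-143 (5p higher in 0 of 3) and 4.06e-06 for miR-22 (0 of 3). It was 0.244 for miR-361, 0.273 for miR-872 and 0.0654 for miR-350, which with miR-375 made up the 4 hairpins not past the threshold. The median size of the log2 ratio was 5.14, and 126 hairpins had the same sign in all 3 mice. In 47 hairpins 1 arm stood at the floor throughout, so their ratios depend on the scale's floor. The ratios compare strands within a library and do not account for unequal capture of different sequences.

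**Figure D2:**
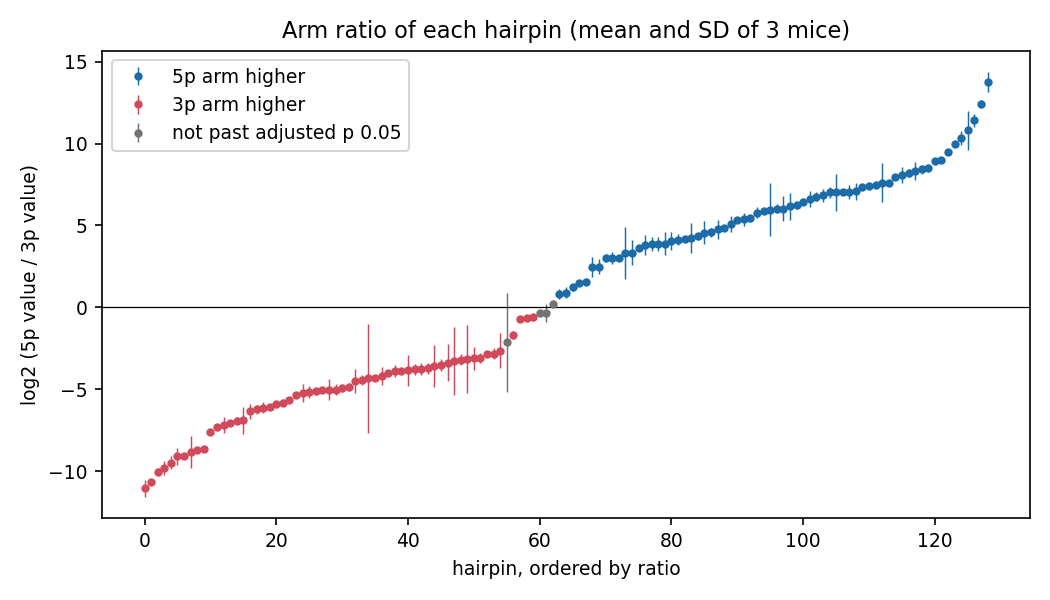
Log2 ratio of 5p to 3p value (mean, with bars of 1 SD of 3 mice) for 129 hairpins ordered by ratio, coloured by the limma call. The ratios run from -11.06 for miR-143 to 13.76 for miR-10b, and 4 hairpins in grey did not pass.

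Muscle-enriched and epithelial miRNAs were among those with the widest spread between the 3 mice. The muscle-enriched miR-133b-3p had the largest SD, 3.32 log2 units, with 3.83 in mouse 1, 9.49 in mouse 3 and 9.65 in mouse 9. miR-375-3p, known from pancreatic islets and neuroendocrine cells, had an SD of 3.02, with 8.90 in mouse 1, the floor of 3.32 in mouse 3 and 4.12 in mouse 9. miR-133a-3p had an SD of 2.47, with 11.94, 16.38 and 16.02 in mice 1, 3 and 9. miR-196a-5p, a promoter of beige adipocytes, had an SD of 2.43, with 7.17, 8.73 and 3.96. The epithelial miR-200b-3p had an SD of 2.27, with 8.40, 7.73 and 4.19.

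At the steady end, among the 100 most abundant, miR-30a-5p had equal values in the 3 mice and miR-92a-3p an SD of 0.02 log2 units. miR-98-5p had an SD of 0.04, miR-186-5p of 0.05 and miR-365-3p of 0.05. These small SDs follow in part from the nearly common set of values that the columns hold. The median SD of the 194 miRNAs was 0.22, with 164 below 0.5 and 11 above 1. Of those 11, 4 belong to the epithelial list and 2 to the striated muscle list fixed before the data were examined.

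By limma's variance test with a prior trend, 0 of 194 miRNAs varied more than others at their level after Benjamini-Hochberg adjustment. The smallest adjusted p was 0.773, for miR-133b-3p and miR-133a-3p, and 7 miRNAs had an unadjusted p below 0.05 where chance gives 9.7. On simulated data this test recovered 0 of 10 variable miRNAs among 194, so its count of 0 does not show that the mice were alike. With limma's robust prior, chosen after the data were seen and recovering 10 of 10 in the same simulation, miR-133a-3p and miR-133b-3p passed with an adjusted p of 0.00998 each and 12 miRNAs had an unadjusted p below 0.05. That simulation gave all unchanged miRNAs the same noise, unlike these data, so it does not show how often the robust prior calls falsely here.

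**Figure D3:**
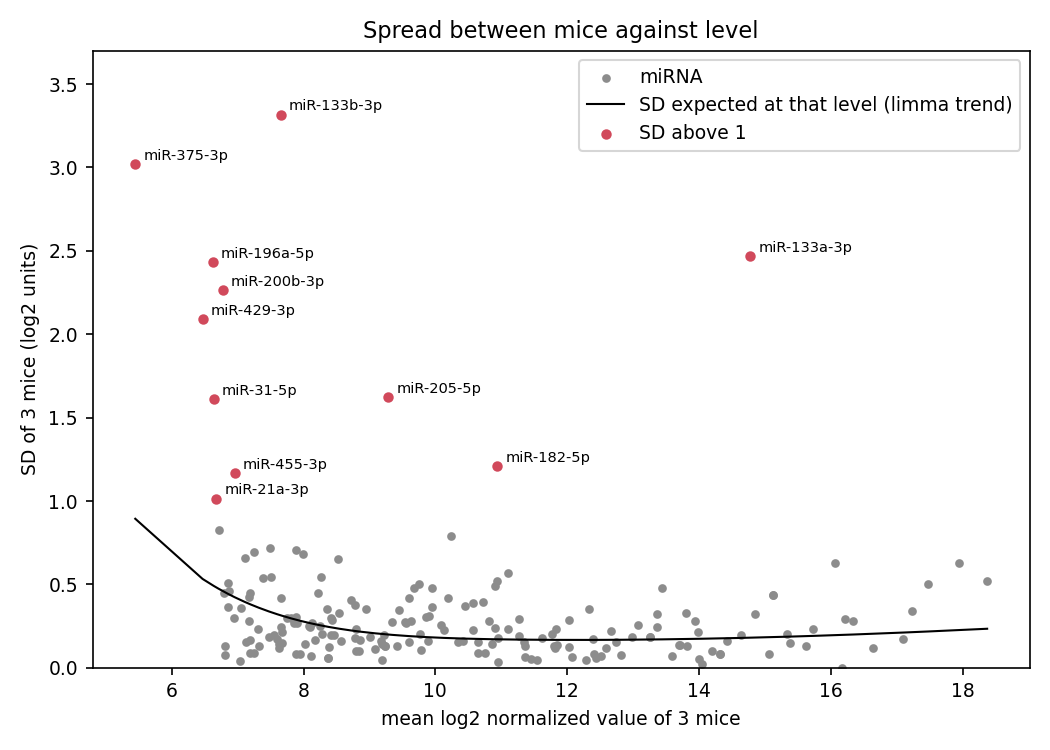
SD of the log2 value over the 3 mice against mean log2 value, 1 point per miRNA for 194 miRNAs, with the SD that the limma trend expects as a line. The 11 named miRNAs have an SD above 1, from miR-133b-3p at 3.32 down, and the median of all is 0.22.

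miRNAs known to steer adipocyte formation stood high in this fat. All 17 of the adipogenesis-promoting list were above the floor in the 3 mice, with a median of 12.59 log2 units, led by miR-143-3p, miR-30a-5p, miR-378a-3p and miR-30d-5p. Of the 20 adipogenesis-inhibiting miRNAs 17 were above the floor and 3 at it, with a median of 12.23, led by let-7c-5p, let-7a-5p, let-7f-5p and miR-27b-3p. Both medians exceeded all of 10000 random lists of the same size. The promoting list stood above the inhibiting one by 0.36 ± 0.20 log2 units, in 3 of 3 mice (SD, n = 3), and the two-sided exact sign-flip p was 0.25, the smallest that 3 mice allow. The inhibiting median includes its 3 members at the floor, which lower it. Among its 17 other members in mouse 9 the middle value was 12.59 (let-7e-5p), above the promoting median of 12.45. The direction in 3 of 3 mice therefore depends on the members at the floor.

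miRNAs tied to thermogenic brown and beige fat were largely present. Of 14 promoting miRNAs 12 were above the floor in all mice, with a median of 10.23 log2 units, led by miR-26a-5p, miR-378a-3p, miR-30c-5p and miR-30b-5p (11.85 ± 0.13). The paired miR-365-3p averaged 11.54 ± 0.05 and miR-193b-3p 10.93 ± 0.52. The cold-responsive miR-455-3p averaged 6.95 ± 1.17, with 7.86, 7.37 and 5.64 in mice 1, 3 and 9, and miR-455-5p 3.57 ± 0.44, above the floor in mouse 3 alone. Of 10 inhibiting miRNAs 9 were above the floor, with a median of 12.26, led by miR-27b-3p, miR-133a-3p, let-7i-5p (13.94 ± 0.28) and miR-125b-5p (13.82 ± 0.13), and miR-34a-5p averaged 9.34 ± 0.28. The median of the promoting list stood below that of the inhibiting one, the difference being -2.04 ± 0.63 log2 units, with promoting higher in 0 of 3 mice (two-sided exact sign-flip p 0.25, the smallest possible). The summed share went the other way, at 15.9% ± 5.39 for the promoting list and 5.31% ± 1.73 for the inhibiting one (SD, n = 3). That direction rests on miR-26a-5p, which alone held 11.2% ± 5.33. Without it the promoting share would be below the inhibiting one. In the inhibiting list miR-133a-3p held 2.15% ± 1.77. Both list medians exceeded all of 10000 random lists drawn from all miRNAs listed, most of which sit at the floor. Against random lists of miRNAs seen in at least 1 mouse, the promoting list stood at percentile 98.7 and the inhibiting list at 99.8.

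Vessel, stromal and blood-cell miRNAs were present at different levels. All 6 endothelial miRNAs were above the floor, with a median of 11.28, led by miR-126-3p (13.37 ± 0.32), miR-126-5p (12.67 ± 0.22), miR-221-3p (11.62 ± 0.18) and miR-222-3p (10.94 ± 0.18). All 10 stromal and smooth muscle miRNAs were too, with a median of 9.40, led by miR-143-3p, miR-145a-5p (14.20 ± 0.10), miR-199a-3p (13.25 ± 0.19) and miR-199a-5p (10.43 ± 0.16). Of 13 leukocyte and macrophage miRNAs 8 were above the floor in all mice and 3 at it, with a median of 6.15. They were led by miR-21a-5p (13.70 ± 0.14), which many cell types express, the lymphocyte miR-150-5p (12.81 ± 0.08), miR-342-3p (10.58 ± 0.22) and miR-142-5p (9.86 ± 0.30). The median of the leukocyte list stood below that of the endothelial one, the difference being -5.16 ± 0.58, with leukocyte higher in 0 of 3 mice (two-sided exact sign-flip p 0.25, the smallest possible). The summed shares were nearly equal, at 1.01% ± 0.0301 for the leukocyte list and 1.01% ± 0.115 for the endothelial one (SD, n = 3). Most of the leukocyte share, 0.553% ± 0.0529, was miR-21a-5p, so the equality is not one of leukocyte-specific miRNAs. The largest endothelial member, miR-126-3p, held 0.446% ± 0.106. Of 4 erythroid miRNAs 3 were above the floor in all mice, with a median of 8.92, led by miR-486-5p, miR-451a (12.33 ± 0.35), miR-144-5p (5.50 ± 0.85) and miR-144-3p (3.49 ± 0.29).

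miRNAs of the testis, hepatocyte and pancreas lists were mostly at the floor, while several neuronal, striated muscle and epithelial miRNAs were not. In the testis and germ cell list 20 of 23 were, the others being miR-34c-5p (7.67 ± 0.15), miR-34b-3p (4.13 ± 0.05) and miR-34c-3p (3.86 ± 0.47). Both hepatocyte miRNAs, miR-122-5p and miR-122-3p, stood at the floor, as did 3 of 4 pancreas miRNAs, miR-375-3p being the exception. Of 9 neuronal miRNAs 5 were at the floor, and the others were miR-128-3p (8.27 ± 0.54), miR-138-5p (7.66 ± 0.25), miR-129-5p (5.20 ± 1.09) and miR-9-5p (4.56 ± 0.88). In the striated muscle list miR-133a-3p and miR-133b-3p were above the floor in all mice, miR-1a-3p averaged 4.10 ± 1.24 and miR-208b-3p 3.95 ± 1.09, and the median was 3.95. The epithelial list had 6 of 10 above the floor in all mice and a median of 6.62, led by miR-182-5p (10.94 ± 1.21), miR-203-3p (9.54 ± 0.27), miR-205-5p (9.28 ± 1.62) and miR-183-5p (7.90 ± 0.27).

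miRNAs reported to rise or fall in obese fat were both abundant, so their levels here do not separate the 2 lists without a control diet. The raised list had a median of 10.22, led by miR-27b-3p, miR-21a-5p, miR-27a-3p (12.43 ± 0.06) and miR-221-3p, with 12 of 14 above the floor in all mice. The lowered list had a median of 11.34, led by miR-26a-5p, miR-143-3p, miR-30a-5p and miR-148a-3p (14.32 ± 0.08), with 15 of 15 above it. The raised list shares 7 members with the leukocyte list, and the lowered list shares 7 with the adipogenesis-promoting list.

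Of the 16 lists, 11 had a median at or above the 97.5 percentile of random lists drawn from all miRNAs listed. The leukocyte list stood at percentile 99.8, the epithelial list at 99.7, the erythroid list at 99.1 and the striated muscle list at 94.5. Drawn only from miRNAs seen in at least 1 mouse, the random lists put 7 lists at or above that percentile, since most listed miRNAs sit at the floor. The stromal and smooth muscle list, at percentile 100 before, then stood at 93.4, the leukocyte list at 28.4, the epithelial list at 41.8, the erythroid list at 79.0 and the striated muscle list at 3.13. A percentile describes these libraries and is not a test.

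The median deviations of 3 lists, over members seen in at least 1 mouse, differed between mice by more than those of nearly all random lists matched on level. The median deviation of the striated muscle list from the mean of the mice was -0.78, 1.44 and 1.24 log2 units in mice 1, 3 and 9. In that list miR-133a-3p and miR-133b-3p stood 4.26 and 5.74 log2 units higher in the mean of mice 3 and 9 than in mouse 1, and miR-1a-3p, miR-208b-3p and miR-206-3p stood 1.16, 0.94 and 0.25 higher at values of at most 5.53. The other 2 members were at the floor in all mice. The median deviation of the epithelial list was 0.35, 0.97 and -1.35, and that of the brown and beige promoting list 0.14, 0.40 and -0.36. Their ranges of 2.21, 2.32 and 0.77 each lay at percentile 99.98 of 10000 random lists matched on level, and the other 11 lists tested lay below percentile 99. The random lists drew each miRNA separately, while these lists hold members of one transcript, so the percentiles may be too high. Adjusted over the list alone, limma's variance test called miR-133a-3p and miR-133b-3p, the only 2 of the 7 striated muscle members that were tested. Both also belong to the brown and beige inhibiting list, where 9 members were tested, and were called there too. The test called 0 members of each of the other lists. Over all 194 miRNAs it called 0.

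The epithelial and brown results rest on mouse 9 and the muscle result on mouse 1. Without mouse 9 the epithelial list lay at percentile 95.1 and the brown and beige promoting list at 79.0, and without mouse 1 the striated muscle list lay at 64.9. The brown and beige promoting list shares 2 members, miR-182-5p and miR-203-3p, with the epithelial list, and without these its range of 0.77 lay at percentile 99.96.

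**Figure D4:**
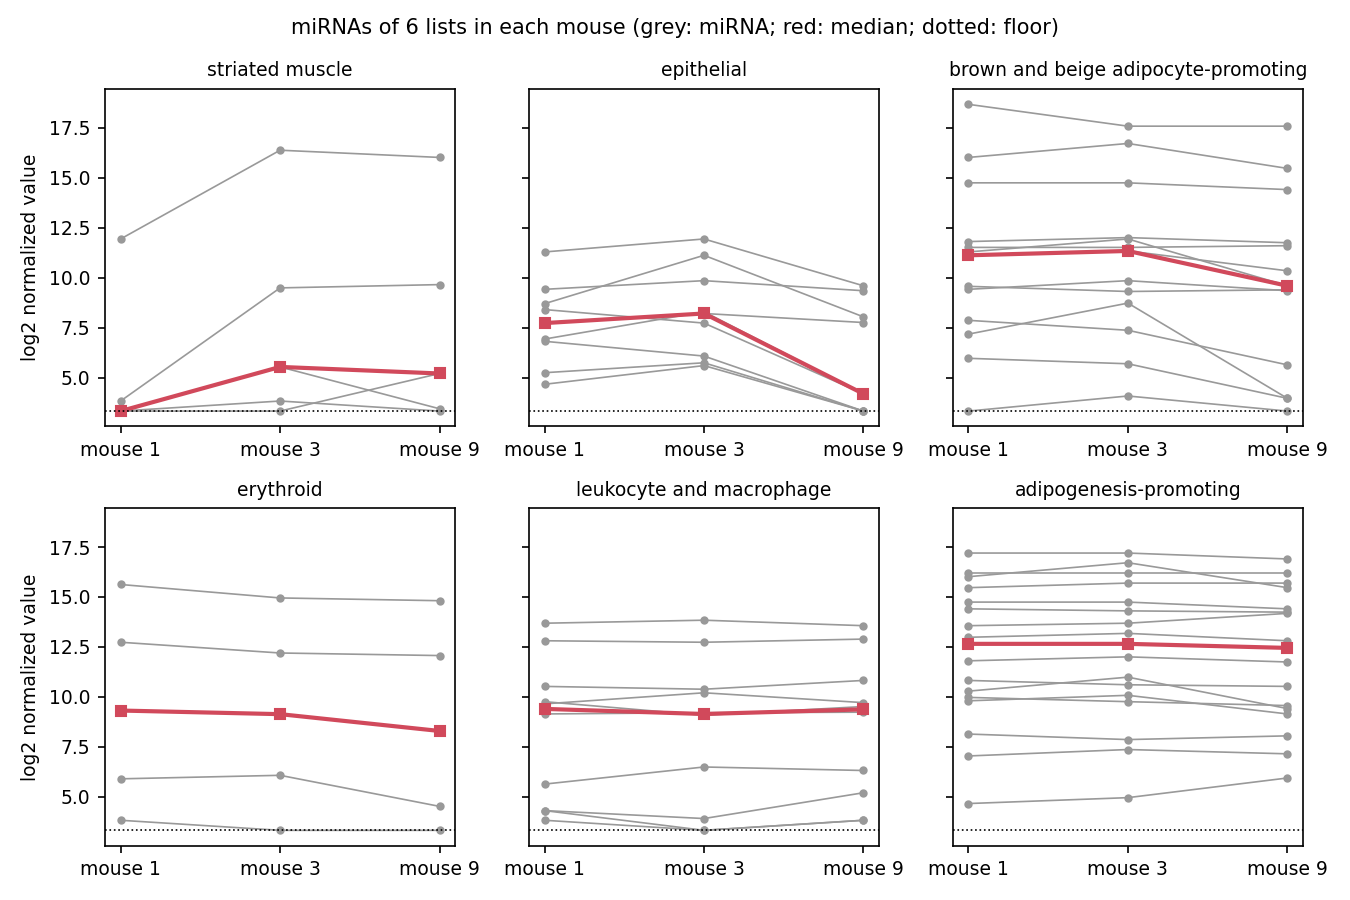
Log2 normalized value of the members of 6 lists in mice 1, 3 and 9, for members above the floor in at least 1 mouse. Each grey line joins 1 miRNA, red squares are the median of the members drawn and the dotted line is the floor at 3.32. miR-133a-3p and miR-133b-3p are low in mouse 1, and most epithelial members are low in mouse 9.

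At the median, miRNA pairs of one genomic cluster deviated together between mice more than random pairs did. Over 61 pairs of 50 clustered miRNAs, the median distance between profiles was 0.29 log2 units against 0.47 for random pairs matched on level. Not every pair moved together: miR-193b-3p was lowest in mouse 9 at 10.34, where its cluster partner miR-365-3p was highest at 11.60. miR-365-3p also comes from Mir365-2 on chromosome 11, outside the cluster on chromosome 16. Its value mixes these loci, so this pair does not show how 1 transcript behaved. The one-sided permutation p was 0.0001, the smallest that 10000 sets allow. The observed pairs share miRNAs, while the random sets drew both ends of each pair separately. This p and those that follow may therefore be too small. With a mean of at least 1000 required, the p was 0.12. Without the imprinted Dlk1-Dio3 region, an alternative chosen after the data were seen, it was 0.044, and without mice 1, 3 and 9 in turn 0.015, 0.0004 and 0.022.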

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

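The alternatives chosen after the data were seen were the robust prior, identical rows counted once, pseudocount 40, deposited values with 10 added for the arms, all those of the list contrasts, clusters without the Dlk1-Dio3 region, and list ranges between mice or clusters with a mouse left out. The share of the top 10 miRNAs was 63.6% with values as deposited and 65.2% with identical rows once, against 63.9%. The number of miRNAs seen in all 3 mice was 1251 as deposited, where every value exceeds 0, and 174 at 100 or more, against 287. With a mean of at least 1000, 67 hairpins were left and 39 and 28 had the 5p or 3p arm higher, fewer hairpins being tested. The robust prior called 2 miRNAs in place of 0. Random lists from miRNAs seen in at least 1 mouse put 7 lists at or above the 97.5 percentile in place of 11. Leaving out each mouse left 1 to 4 lists at or above the 99 percentile for the range between mice, against 3: 1 without mouse 9, 2 without mouse 1, and 4 without mouse 3, where the erythroid list joined. Clustered pairs gave a one-sided permutation p of 0.12 with a mean of at least 1000, with a cause that was not tested. The lowest rho between mice was 0.943 with no filter, 0.962 with a mean of at least 1000 and 0.957 as deposited, against 0.960. The other 137 alternatives kept counts within 1.5 times, values within the spread between mice, or tests on the same side of the threshold, and no result turned its direction. Among them, detection at 10 or more gave 241 miRNAs, and pseudocount 40 put 4 lists at or above the 99 percentile. Without mice 1, 3 and 9 in turn, 4, 7 and 3 arm calls lost significance. The unknown depth limits what a value at the floor shows.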

Other observations

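Members of one genomic cluster, and the strands of some hairpins, differed widely in level in this fat. The imprinted Dlk1-Dio3 region had 18 of 45 miRNAs above the floor in all mice, led by miR-127-3p at 13.44 log2 units, and the Sfmbt2 intron, a placental cluster, had 17 of 18 at the floor. In the growth-promoting miR-17 to miR-92a cluster miR-92a-3p averaged 14.04 while miR-18a-5p stood at the floor of 3.32. miR-451a averaged 12.33 and its neighbour miR-144-3p 3.49, and the leukocyte miR-142-5p averaged 9.86 and miR-142-3p 3.82. Of 27 clusters other than that of miR-1a and miR-133a, 11 had a gap above 4 log2 units between hairpins, and the largest was 10.72. Some members also come from a hairpin elsewhere, such as let-7c-5p from chromosomes 16 and 15. A gap need not therefore lie within 1 transcript.

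All of the tests of explanations that follow were chosen after the results were seen, and the bounds of the muscle, epithelial and normalization tests were reworded after their values were known. One group was analysed here and the labels name no factor within it, so no biological explanation was tested, and muscle or epithelial tissue is weighed as a mixture in the sample. Quantile normalization, read from the values and not stated by the sources, would by construction keep the order of miRNAs within a mouse and set the size of differences between mice.

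miR-133a-3p stood 21.7 times higher in mouse 3 and 16.9 times higher in mouse 9 than in mouse 1, and miR-133b-3p and miR-133a-5p were higher by 5.74 and 3.51 log2 units in the mean of mice 3 and 9. Its rank was 54 in mouse 1 against 8 and 10, a difference of 44, which restates the difference in value, since the columns share nearly one set of values, and so tests nothing about the authors' normalization; how far that step set the size stays open. Striated muscle in the samples of mice 3 and 9 may be a source, where the median change of the other 5 muscle miRNAs was 0.25, with 2 of them at the floor throughout and miR-1a-3p, miR-208b-3p and miR-206-3p higher by 1.16, 0.94 and 0.25. Muscle would bring miR-1a-3p of the same transcripts, which stood below miR-133a-3p by 11.71 ± 1.23 (SD, mice 3 and 9). In the means of all 3 mice this gap was 10.68, while the largest gap of another cluster was 10.72 and the median 2.90. On like samples the gap therefore did not exceed that of every other cluster. Low levels near the floor exclude nothing and whether miR-1a-3p was under-read was not tested, so muscle stays open.

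Epithelial-list miRNAs stood lower in mouse 9, by a median of 2.02 log2 units below the mean of mice 1 and 3, and 8 of 9 members above the floor were lowest there, where random lists have a median of 2. Several members share a transcript, which the random lists do not copy, so the 8 are not independent. The ranks of the epithelial-list miRNAs moved by a median of 112.5 (44.8 for the 6 above the floor in all mice), which again restates the values, so how far the authors' normalization set the size stays open. Less epithelial tissue in the sample of mouse 9 is a candidate explanation. Of 6 members with a mean of at least 100, however, 4 were lower by at least 1 log2 unit, while miR-183-5p, from the transcript of miR-182-5p, and miR-203-3p were nearly level with the other mice. Whether other cells supply those 2 miRNAs was not tested. Cells that supply miR-183-5p would bring miR-182-5p of the same transcript, yet these were lower by 0.21 and 2.02 log2 units. Tissue loss stays open.

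Low GC content of an arm may lower its reading and so part members of one transcript. Across 61 miRNAs in 25 clusters, level and GC of the side of the hairpin that holds the arm, both relative to the cluster mean, had a Spearman rho of 0.150 (one-sided permutation p = 0.18). With the Dlk1-Dio3 region included, rho was 0.222 over 100 miRNAs in 26 clusters (one-sided permutation p = 0.026). The relation across miRNAs, which are not independent, was weak and differed with the clusters included, so GC stays open.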
